A study of Oryza sativa Indica Group with 31 samples.

How the data were processed

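Roots of 10-day-old hydroponic seedlings of 6 rice genotypes were sampled after 24 h with 0 or 50 µM arsenate, and total RNA was labelled as biotinylated cRNA and hybridized to the Affymetrix rice genome array. The 31 arrays form 12 groups of 2 or 3 biological replicates, 1 group per genotype and treatment, taken from the sample titles. The only values available were the deposited probeset intensities on the log2 scale, which the authors made with RMA (background correction, quantile normalization and probeset summary). The version of RMA and whether the arrays were processed together are not given in the sources used here. The values show that the genotypes were not all normalized together. The sorted values of the arrays of a genotype lie within 0.143 to 0.328 log2 units of each other, while those of other genotypes lie up to 0.27 to 5.5 from BRG-12. For CN1646-5, at 0.27, a scale apart from that of BRG-12 is not shown, since the arrays of BRG-12 lie up to 0.302 from each other. The median value is 4.20 in BRG-12, 3.62 in BRG-15, -0.22 in BRG-20, 4.24 in CN1646-5, 4.09 in NAYANMONI and 0.07 in CN1646-2. Changes were therefore taken within a genotype, while levels were not compared between genotypes beyond counts. The size of a change can also depend on the scale. Quantile normalization of all arrays moved the probesets counted as changed with arsenate in BRG-20 from 10593 to 17023. Sizes and counts of changes are compared between genotypes with this limit. No raw files, detection calls or genome came with the values, so no gene positions are given.

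Of 57381 probesets, 123 control probesets were left out and 57258 were tested, with no filter on low values. The platform annotation gives 1 gene symbol for 22436 probesets, several for 95 and none for 34727, which are unnamed here. For gene-level results 1 probeset stood for each of 17905 genes, the one with the highest mean over all arrays, with cross-hybridizing probesets used only where a gene had no other. Of these genes, 3444 have several probesets and 2457 have a name beyond a locus number.

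The test was limma 3.58.1 in R 4.3.3, with 1 mean per group, contrasts, empirical Bayes moderation and Benjamini-Hochberg adjustment per contrast, and an adjusted p under 0.05 counted as called. Adjusted p-values in the text come from limma. The number of called probesets that changed at least 2-fold is given beside each count. The comparisons were arsenate minus control in each genotype, the unweighted mean of these 6 responses, a moderated F test and 15 pairwise contrasts for differences between the responses, an F test among the 6 control groups, and CN1646-2 against CN1646-5 controls. The fit pools the spread over all groups, so groups of 2 arrays are assumed to vary like the others. This assumption is in doubt, since the median standard deviation per probeset was 0.0576 to 0.0738 in groups of 2 arrays and 0.118 to 0.133 in groups of 3. Standard errors are those of the fit. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

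Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and, as an alternative, with an estimated correlation per list. There are 45 lists with 1086 genes. Their themes, the comparisons, the rule for named genes and the alternatives were fixed before the data were examined. The annotation turned out to hold no descriptions, so the lists' word patterns matched almost nothing. The lists were rebuilt from gene symbols and synonyms after the annotation was read and before any test was run. Some genes are in several lists. The phytoalexin and cytochrome P450 lists share members, CYP71Z7, CYP76M5 and CYP99A2 among them, so their calls are not independent in any comparison. The genes named are the 15 largest rises and 15 largest falls of the mean response among called genes with the same sign in all 6 genotypes, and per genotype the 10 largest rises and 10 largest falls among called genes whose arsenate arrays all lie beyond all control arrays. They also include the 10 genes with the widest range between genotypes, up to 4 members per list with the smallest adjusted p, and a panel of 19 arsenic, silicon and phosphate transport genes, of which 15 could be matched by name. Because most genes carry only a locus number, the rule was applied once over all genes and once over the genes with a name, and the text gives mainly the latter. The rule was not applied to the 2 comparisons of control roots, where the scale differs between most genotypes.

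The steps were tested on simulated arrays with known changes. Each probeset had 1 spread, pooled over all groups of real arrays as in the fit, and noise was independent between probesets. Groups that differ in spread and correlated genes were not simulated, so the shares below need not hold for the real arrays. Between 49.3% and 72.9% of 1.5-fold changes were recovered in a single genotype and at least 95.2% of 2-fold changes, and at most 7.65% of the calls in a genotype were false. A list raised by 0.3 was called in every comparison, and in the mean response 1 other list, which was not raised, was called too. The control probesets were used to check the arrays. Replicate numbers did not pair control with arsenate arrays, so no pairing was used. The alternatives were quantile normalization of all arrays, a shift of each array to a common median, the probesets above the median level, an intensity trend, array weights, a replicate block, a fit of 1 genotype alone, an additive model, an estimated correlation, the mean of all probesets of a gene, and each array left out in turn. Leaving out whole genotypes from the mean, and averaging probesets for the named genes, were added later.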

Results

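Gene expression was measured in the roots of 6 rice genotypes, the breeding lines CN1646-2 and CN1646-5, NAYANMONI, and BRG-12, BRG-15 and BRG-20. Seedlings grew for 10 days in hydroponic medium and then spent 24 h with 50 µM or 0 µM arsenate, the pentavalent form of arsenic that enters roots through phosphate transporters. Each of the 31 samples was hybridized to 1 Affymetrix rice genome array, and the values are log2 probeset intensities. BRG-12 had 2 control and 3 arsenate arrays, BRG-15 and NAYANMONI had 2 and 2, and BRG-20, CN1646-5 and CN1646-2 had 3 and 3. Altogether 15 control arrays were set against 16 arsenate arrays in 12 groups. The lowest Pearson r between replicates of a group, taken across probesets, was 0.991, and the median standard deviation per probeset within a group lay between 0.0576 and 0.133 log2 units. Some replicates share many exactly equal values, up to 10657 of 57258 probesets between the 2 BRG-12 control arrays. Such ties lower the measured spread, and their source was not tested. The number of arrays limits the precision of every value. The p-values measure the spread between these samples, because the labels call them biological replicates without saying whether the plants or the cultures were separate. BRG-20 arsenate replicate 3 carries a breeding-line description that the other BRG-20 arrays lack, with the parents that the labels give to the CN1646 lines. It was kept in the group of its title, and its r with the other BRG-20 arsenate arrays was 0.99237 and 0.99488. All changes below are arsenate minus control on the log2 scale, and all p-values of genes are adjusted p-values from limma.

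The mean of the 6 genotypes' responses measures the average change, and genotypes can depart from it. Its standard errors and p-values rest on the spread within groups, not between genotypes, so they hold for these 6 genotypes only. Glutathione S-transferase genes and small heat shock protein genes were higher with arsenate on average. Enzymes of diterpenoid phytoalexin synthesis, pathogenesis related proteins, aquaporins, cytochrome P450s and photosynthesis genes were lower on average, although the phytoalexin enzymes were called higher in CN1646-2. The calls of the pathogenesis related proteins, the aquaporins and the P450s depended on which genotypes entered the mean. These lists were also called with an estimated correlation between genes. Of 57258 probesets, 5593 were higher and 5209 lower, 10802 in all (18.9%), and 222 of them changed at least 2-fold in the mean. The count was 4756 with the additive model of genotype and treatment and 12932 without NAYANMONI. The balance of rises and falls rests on the scaling, and after a shift to a common median it was 4865 higher and 5302 lower. Of 17905 genes, 4221 rose and 3695 fell, and 149 changed at least 2-fold, 85 upward and 64 downward. The sign was the same in all 6 genotypes for 651 called genes, 412 higher and 239 lower, with no chance level computed. In separate tests, 31 genes were called higher in all 6 genotypes, 18 lower in all, and 8175 higher in 1 and lower in another. These counts rest on the NAYANMONI labels, whose exchange was not excluded.

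**Figure D1:**
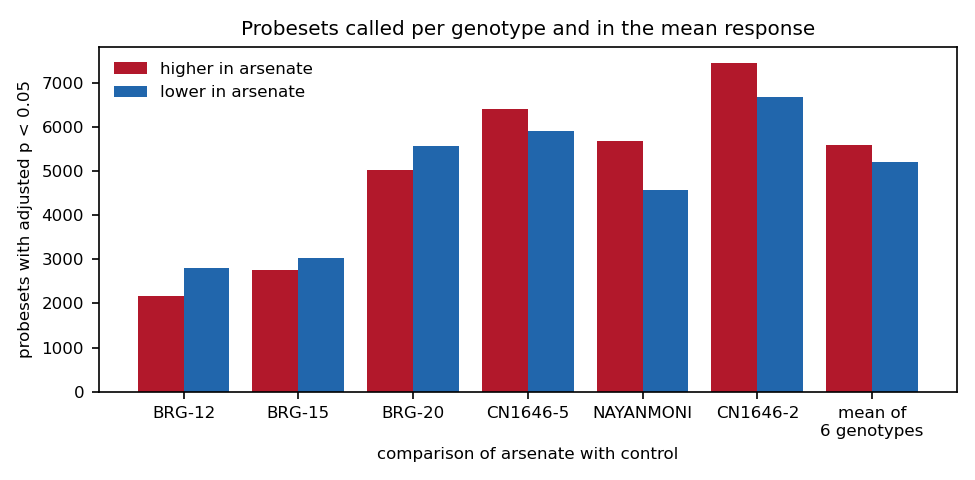
Bars give the number of probesets, of 57258 tested, called higher or lower with arsenate at an adjusted p under 0.05 in each genotype and in the mean of the 6 responses. The total runs from 4973 in BRG-12 to 14115 in CN1646-2, and the genotypes have different numbers of arrays.

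Among genes with the same sign in all 6 genotypes, the largest mean rise was that of the small heat shock protein gene HSP18.1 (LOC4332361), at 2.68 with a standard error of 0.0619 (adjusted p = 8.72e-22), followed by HSP17.4 with 2.60 and LOC4328933 with 2.44. The size of the HSP18.1 change differed between genotypes (adjusted p = 5.64e-20 for the difference). It was 5.82 in BRG-20, 6.32 in CN1646-2, 2.83 in CN1646-5 and 0.80 in BRG-12, and was not called in BRG-15 (0.12) or NAYANMONI (0.17). GSTZ5 (LOC4332455), a glutathione S-transferase gene, was called higher in all 6 genotypes, with a mean of 2.35 and a standard error of 0.0827 (adjusted p = 3.63e-18). Its values ran from 0.56 in NAYANMONI to 3.81 in BRG-20. The NAYANMONI call (adjusted p = 0.0465) was near the threshold. It ended after a shift to a common median (adjusted p = 0.052) and without any 1 NAYANMONI array (adjusted p = 0.11 to 0.16). LOC4334183 rose by 2.36, and both it and LOC4328933 were called higher in all 6 genotypes. The LOC4328933 call in BRG-15 (0.53, adjusted p = 0.0346) ended under quantile normalization (adjusted p = 0.336), after the median shift (adjusted p = 0.059) and without any 1 BRG-15 array. Named genes with smaller mean rises were GST1 (1.28), the Casparian strip membrane protein-like gene OsCASPL1B1 (1.26), BLE3 (1.16) and the dehydrin gene RAB16B (1.10). Further rises were those of ADIPOR1 (0.97), pla2-II (0.85), DAO (0.81), WBC5 (0.74) and LOGL6 (0.58). The laccase gene LAC3 rose by 1.11 and was called higher in all 6 genotypes.

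The largest mean fall was that of LOC4347027 (-2.05, standard error 0.039, adjusted p = 1.69e-23), which was called lower in all 6 genotypes. BURP16 fell by 1.54, from -3.22 in BRG-12 to -0.16 in BRG-15, where it was not called, and the sugar transporter gene SWEET1A (-1.33) was called lower in all 6 genotypes on 1 probeset, while its other probeset gave 0.02. The SWEET1A call in BRG-12 ended without control replicate 1 (adjusted p = 0.0525), control replicate 2 (adjusted p = 0.271) or arsenate replicate 1 (adjusted p = 0.138). AOS3 (-0.87) and LOX3 (-0.69), each of a family with a part in jasmonate synthesis, fell, while the jasmonate list as a whole was not called (14 of 37 genes higher and 9 lower, adjusted p = 0.972). METK3 (-0.74), IRL1 (-0.74), PLA2-III (-0.74), MYB2 (-0.71), TOE1 (-0.58) and the laccase gene LAC7 (-0.68) fell as well. The magnesium chelatase subunit gene CHLH fell by 0.71 on 1 probeset (0.06 on the other), and the light-induced gene LIR1 (-0.70) fell too. Of the 15 largest rises and 15 largest falls over all genes, 3 rises and 2 falls belonged to genes with a name, so most of the largest changes with the same sign in all genotypes lie in genes known here only by a locus number.

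Of 45 gene lists, 13 were called in the mean response, 7 higher and 6 lower, and 7 of these were also called with an estimated correlation between genes. Of list members, 615 were called when adjusted over all genes and 629 when adjusted over the list alone, and a gene in several lists counts in each. The glutathione S-transferases were higher (5 of 6 genes higher, 0 lower, median 0.72, adjusted p = 4.85e-06, and adjusted p = 0.0192 with an estimated correlation), and besides GSTZ5 and GST1 the members GSTU6 (0.77) and GST-I (0.67) rose. The small heat shock proteins were higher (13 of 19 genes higher and 2 lower, median 0.45, adjusted p = 2.4e-06, and adjusted p = 0.0124 with an estimated correlation), with HSP18.6 at 1.91 and HSP17.7 at 1.01. The other 2 probesets of HSP18.6 gave 0.09 and 1.48. The heat shock factors were higher (10 of 20 genes higher and 2 lower, median 0.16, adjusted p = 0.0244, and adjusted p = 0.356 with an estimated correlation). HSFA2A rose by 2.25, with 0.88 and 2.27 on its other 2 probesets, and HSFA3 rose by 0.80. HSFA2C fell by 0.78 on 1 probeset, a sign that turned when its probesets were averaged (0.08). Among the brighter genes alone the call of the factors ended, with a median of 0.04 (adjusted p = 0.773). The large chaperones were higher (13 of 30 genes higher and 4 lower, median 0.04, adjusted p = 0.0314, and adjusted p = 0.461 with an estimated correlation), led by CLPB1 (1.74) and CLPB-M (1.37). This call ended among the brighter genes (adjusted p = 0.15), with the replicate block (adjusted p = 0.0562), with the probesets of each gene averaged (adjusted p = 0.0559) and with NAYANMONI left out (adjusted p = 0.0559).

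Lists of protein turnover and growth were higher too. The ribosomal proteins were higher (19 of 23 genes higher and 2 lower, median 0.16, adjusted p = 4.71e-05, and adjusted p = 0.0688 with an estimated correlation), CYC07 with 0.36 and RPS26 with 0.33. So were the proteasome and ubiquitin genes (13 of 24 genes higher, 0 lower, median 0.10, adjusted p = 0.00618, and adjusted p = 0.253 with an estimated correlation). The ribosomal median was 1.02 in CN1646-2, while the list was called lower in NAYANMONI (-0.24). In single genotypes the proteasome list was called only in BRG-15 and CN1646-2. A mean without CN1646-2 was not computed, so how far these calls rest on that line is not known. Cytokinin genes were higher in the mean (16 of 31 genes higher and 3 lower, median 0.15, adjusted p = 0.00543, and adjusted p = 0.166 with an estimated correlation), among them LOGL3 (0.68), of a family that activates the hormone, and CKX4 (0.61), of a family that degrades it. The diterpenoid phytoalexin enzymes were lower (12 of 16 genes lower, 0 higher, median -0.32, adjusted p = 3.83e-05, and adjusted p = 0.00348 with an estimated correlation), with CYP71Z7 at -0.47, CPS4 at -0.43 and CYP76M5 at -0.54. The pathogenesis related proteins were lower (11 of 20 genes lower and 1 higher, median -0.18, adjusted p = 0.00123, and adjusted p = 0.017 with an estimated correlation), led by PBZ1 (-0.89) and a chitinase gene, LOC4348631 (-0.89). The germin-like proteins were lower (6 of 9 genes lower, 0 higher, median -0.19, adjusted p = 0.0029, and adjusted p = 0.141 with an estimated correlation), with GER1 at -1.06. The cytochrome P450s were lower (15 of 29 genes lower and 4 higher, median -0.13, adjusted p = 0.012, and adjusted p = 0.0313 with an estimated correlation). This list shares CYP71Z7, CYP76M5 and other members with the phytoalexin list. The aquaporins were lower (12 of 25 genes lower and 3 higher, median -0.10, adjusted p = 0.00315, and adjusted p = 0.0124 with an estimated correlation). CYP88A5 fell with -0.84 and TIP4-1 with -0.56, whereas the aquaporin gene PIP2-4 rose by 0.47. The aquaporin call ended among the brighter genes (adjusted p = 0.0846). With NAYANMONI left out, the mean calls of the pathogenesis related proteins (adjusted p = 0.0559), the P450s (adjusted p = 0.188) and the aquaporins (adjusted p = 0.0559) ended. With BRG-12 and CN1646-5 left out, those of the P450s (adjusted p = 0.464), the aquaporins (adjusted p = 0.545) and the germin-like proteins (adjusted p = 0.33) ended. The photosynthesis list, which also marks shoot tissue in a root sample, was lower (11 of 19 genes lower and 1 higher, median -0.28, adjusted p = 5.23e-05, and adjusted p = 0.0054 with an estimated correlation), with CAB2R at -1.04 and GOS5 at -0.65.

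A panel of genes of silicon, phosphate and arsenic transport was chosen in advance, and 15 of its 19 genes could be matched by name. Lsi1, Lsi2 and Lsi6, silicon channels and transporters that also carry arsenite, fell by 0.35, 0.78 and 0.55 in the mean. By the labels, their direction was not shared. Lsi2 fell in 5 genotypes, with -2.48 in BRG-15, and rose in NAYANMONI (1.88), and Lsi1 rose there by 2.03 and Lsi6 by 2.02 (adjusted p = 4.37e-16, 1.27e-15 and 3.18e-15 for the differences between genotypes). An exchange of the NAYANMONI labels, which would turn these rises into falls, was not excluded. The Lsi2 call in CN1646-5 (-0.26, adjusted p = 0.0467) ended under quantile normalization (adjusted p = 0.274) and after the median shift (adjusted p = 0.0594). Without BRG-12 and CN1646-5 the mean of Lsi6 was 0.03 (adjusted p = 0.792). The metal transporter gene Nramp1 rose by 1.37 in the mean, with 2.98 in BRG-20, 2.32 in CN1646-2 and 2.27 in NAYANMONI. It rose less in BRG-12 (0.68) and was not called in BRG-15 (-0.19) or CN1646-5 (0.16). Of the phosphate transporters, OsPht1;4 rose (0.56), OsPht1;1 (-0.50), OsPht1;2 (-0.50) and OsPht1;8 (-0.20) fell, and OsPht1;6 was not called (0.09, adjusted p = 0.0743). OsPht1;4 and Lsi6 were each measured by a cross-hybridizing probeset alone, so their values may include related genes. The other probeset of OsPht1;1 gave 0.02, and those of OsPht1;8 gave -0.24 and 0.04. The mean call of OsPht1;8 (adjusted p = 0.0316) ended under quantile normalization (adjusted p = 0.0794) and without several single arrays. The phosphate sensors SPX1 (-0.13), SPX2 (-0.28) and SPX3 (-0.14) fell, and PHR2 was not called (0.12, adjusted p = 0.0872). The mean call of SPX3 ended under quantile normalization (adjusted p = 0.114). With the additive model the mean calls of Lsi1 (adjusted p = 0.169), OsPht1;2 (adjusted p = 0.0877), OsPht1;8 (adjusted p = 0.247), SPX1 (adjusted p = 0.299) and SPX3 (adjusted p = 0.0526) ended. The arsenate reductase gene ACR2.1 fell by 0.26, and ACR2.2 was not called (0.08, adjusted p = 0.0598).

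**Figure D2:**
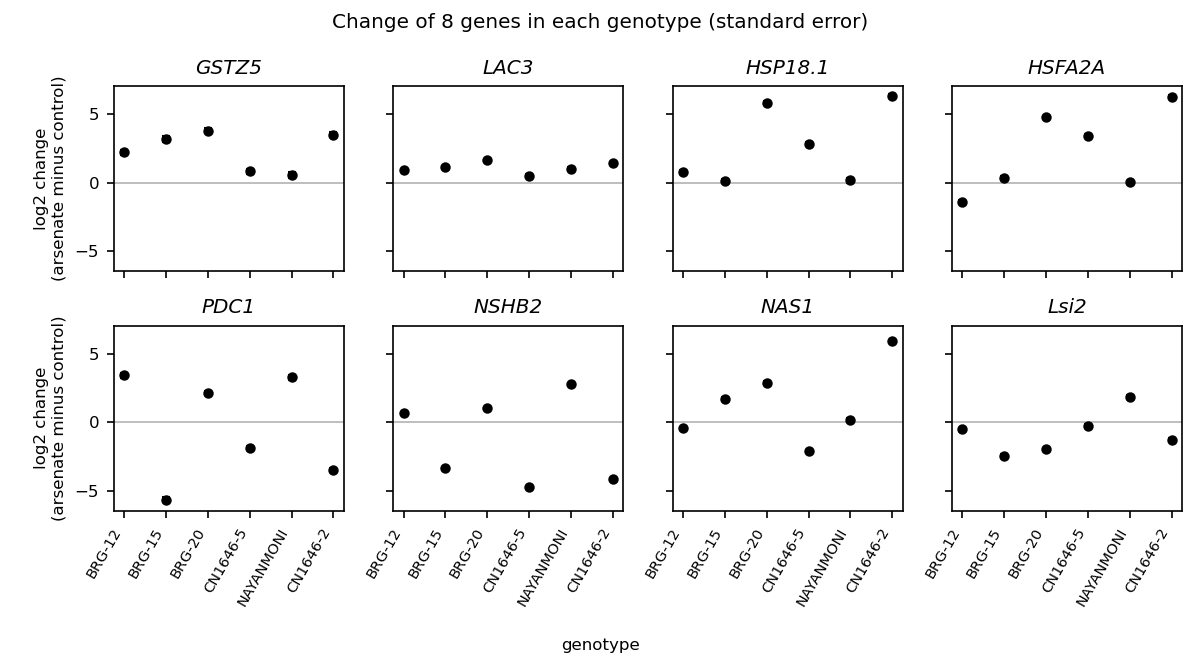
Points give the log2 change of 8 genes, arsenate minus control, in each genotype, with bars for the standard error from limma that are mostly smaller than the points. GSTZ5 and LAC3 lie above 0 in all 6 genotypes, while PDC1 and NSHB2 lie above 0 in 3 genotypes and below 0 in 3.

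BRG-12 asks what arsenate changed in 1 of the 3 BRG genotypes. Phytoalexin and P450 genes, lists that share members, were lower in BRG-12. Fermentation and glutathione S-transferase genes were higher and germin, jasmonate and calcium signalling genes lower with the preset correlation only. For these 5 lists the adjusted p-values with an estimated correlation were 0.153, 0.0744, 0.159, 0.205 and 0.218. Of the probesets, 2164 were higher and 2809 lower, 4973 in all (8.69%), and 1034 of these changed at least 2-fold. The count was 3265 without control replicate 2, 1056 with only the BRG-12 arrays in the fit and 13944 with array weights, so it is poorly fixed. With array weights the balance turned, to 7262 higher and 6682 lower. At the gene level 3755 genes were called, with 225 rises and 299 falls of at least 2-fold, and in 38% of genes every arsenate array lay beyond every control array, where chance gives 20%.

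The largest rises of named genes were those of pyruvate decarboxylase gene PDC1 (3.43, standard error 0.181, adjusted p = 6.2e-14), OsC3H37 (3.33), PDC2 (2.39), GSTZ5 (2.21), LSD1 (1.95), GST1 (1.80), OsCASPL1B1 (1.80), pla2-II (1.78) and the dehydrin gene RAB21 (1.72). The nitrate reductase gene NIA1 rose by 3.11 on 1 probeset, while its other probeset gave -0.04. CML10, TPP7 and HSFB2B also have a second probeset, and it gave 0.02, 0.07 and 0.04. The largest falls of named genes were those of BURP16 (-3.22), the beta-glucosidase gene BGLU34 (-3.16), GER1 (-2.69), DREB1G (-2.58), the calmodulin-like gene CML10 (-2.58), the isocitrate lyase gene ICL (-2.49), PLP2 (-2.23), TPP7 (-1.93), a peroxidase gene, LOC4339222 (-1.93), and HSFB2B (-1.76).

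In BRG-12, 12 lists were called, 3 higher and 9 lower, and 2 of them also with an estimated correlation. Of list members, 343 were called over all genes and 367 adjusted over the list alone. The hypoxia and fermentation genes were higher (6 of 13 genes higher and 1 lower, median 0.24, adjusted p = 0.00306, and adjusted p = 0.153 with an estimated correlation), with Adh2 at 1.19 beside PDC1 and PDC2. The glutathione S-transferases were higher (4 of 6 genes higher, 0 lower, median 0.94, adjusted p = 7.83e-05, and adjusted p = 0.0744 with an estimated correlation), with GSTU6 at 1.64. So were the genes of DNA replication and cell cycle (13 of 81 genes higher and 1 lower, median 0.12, adjusted p = 0.00658, and adjusted p = 0.341 with an estimated correlation). The diterpenoid phytoalexin enzymes were lower (9 of 16 genes lower, 0 higher, median -0.56, adjusted p = 2e-06, and adjusted p = 0.000579 with an estimated correlation), with KSL7 at -1.33, CYP99A2 at -1.12 and CPS4 at -1.08. So were the cytochrome P450s (14 of 29 genes lower and 2 higher, median -0.33, adjusted p = 5.06e-05, and adjusted p = 0.00154 with an estimated correlation). Germin-like proteins were lower (4 of 9 genes lower, 0 higher, median -0.22, adjusted p = 0.00306, and adjusted p = 0.159 with an estimated correlation). Jasmonate genes were lower (9 of 37 genes lower and 2 higher, median -0.13, adjusted p = 0.00644, and adjusted p = 0.205 with an estimated correlation), AOS2 with -1.58. The calcium signalling list was lower (18 of 77 genes lower and 6 higher, median -0.09, adjusted p = 0.00702, and adjusted p = 0.218 with an estimated correlation). The heat shock factors were lower (7 of 20 genes lower and 3 higher, median -0.22, adjusted p = 0.00644, and adjusted p = 0.218 with an estimated correlation), with HSFA2A at -1.42 and HSFB2A at -1.58. Iron homeostasis genes were lower (9 of 29 genes lower and 1 higher, median -0.10, adjusted p = 0.029, and adjusted p = 0.0744 with an estimated correlation), with IRT1 at -1.10. Beta-glucosidases were lower (6 of 27 genes lower and 2 higher, median -0.07, adjusted p = 0.0319, and adjusted p = 0.218 with an estimated correlation). The cellulose synthase family was lower (7 of 29 genes lower and 2 higher, median -0.16, adjusted p = 0.0319, and adjusted p = 0.218 with an estimated correlation). The last 3 calls ended when control replicate 1 was left out (adjusted p = 0.0506, 0.0896 and 0.0575) and when arsenate replicate 1 was left out (adjusted p = 0.0636, 0.0636 and 0.0573). Among the brighter genes the calls of DNA replication (adjusted p = 0.157), heat shock factors (adjusted p = 0.0811), beta-glucosidases (adjusted p = 0.0528) and cellulose synthases (adjusted p = 0.259) ended. Beside these gene changes, the 3' minus 5' difference of the GAPDH control probesets rose by 2.15 with arsenate in BRG-12 and that of actin by 0.893, a measure that grows as RNA is shortened.

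In BRG-15, laccase and other lignin genes were higher, and the silicon transporter genes Lsi1 and Lsi2 fell. Glutathione S-transferase genes were higher and fermentation and aquaporin genes lower with the preset correlation only. For these 3 lists the adjusted p-values with an estimated correlation were 0.0661, 0.0665 and 0.0665. Of the probesets, 2750 were higher and 3037 lower, 5787 in all (10.1%), and 1034 changed at least 2-fold. Each array mattered with 2 per group, and the count was 3621 without control replicate 1, 3811 without control replicate 2, 3708 without arsenate replicate 1 and 3710 without arsenate replicate 2. With array weights it was 10057. Of 4666 called genes, 271 rose and 357 fell at least 2-fold, and the groups did not overlap in 69.9% of genes, where chance gives 33.3%.

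In BRG-15, the named genes with the largest rises were LTP2-B (3.42), the nicotianamine aminotransferase gene NAAT1 (3.25), the laccase gene LAC19 (3.22), GSTZ5 (3.18), Pir7b (3.15), LAC15 (2.49), Osnph1b (2.31), GSTU6 (2.21), the alternative oxidase gene AOX1a and the aluminium transporter gene Nrat1 (2.00). The largest falls of such genes were those of PDC1 (-5.66, standard error 0.199, adjusted p = 1.68e-17), the calcium-dependent protein kinase gene CPDK2 (-4.06), the non-symbiotic hemoglobin gene NSHB2 (-3.36), a peroxidase gene, LOC4344277 (-3.33), PSK2 (-2.49), Lsi2 (-2.48), NIA1 (-2.40), OsPht1;2 (-2.28), the chitinase gene Chib3H-a (-2.11) and HSFA2C (-1.96). The second probesets of GSTU6 and NIA1 gave -0.03 and 0.07.

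In BRG-15, 8 lists were called, 5 higher and 3 lower, and 1 of them, the lignin list, also with an estimated correlation. Of list members, 416 were called over all genes and 444 adjusted over the list alone. Lignin and phenylpropanoid enzymes were higher (12 of 29 genes higher and 2 lower, median 0.15, adjusted p = 0.000235, and adjusted p = 0.00642 with an estimated correlation), with CAD3 at 1.54 and LAC24 at 1.12. Glutathione S-transferases were higher (5 of 6 genes higher, 0 lower, median 0.84, adjusted p = 1.56e-05, and adjusted p = 0.0661 with an estimated correlation). Ribosomal proteins were higher (7 of 23 genes higher, 0 lower, median 0.21, adjusted p = 0.000778, and adjusted p = 0.175 with an estimated correlation), with RPS26 at 0.45. Proteasome genes were higher (6 of 24 genes higher, 0 lower, median 0.18, adjusted p = 0.0155, and adjusted p = 0.301 with an estimated correlation). Genes of DNA replication and cell cycle were higher (12 of 81 genes higher and 4 lower, median 0.15, adjusted p = 0.0349, and adjusted p = 0.664 with an estimated correlation), a call that ended without control replicate 2 (adjusted p = 0.15) and without arsenate replicate 1 (adjusted p = 0.0578). Hypoxia and fermentation genes were lower (7 of 13 genes lower and 1 higher, median -0.77, adjusted p = 0.000235, and adjusted p = 0.0665 with an estimated correlation), with PDC2 at -1.37. Aquaporins were lower (9 of 25 genes lower and 1 higher, median -0.17, adjusted p = 0.0346, and adjusted p = 0.0665 with an estimated correlation), with Lsi1 at -1.65, a call that ended without arsenate replicate 1 (adjusted p = 0.0578). Photosynthesis genes were lower (8 of 19 genes lower and 3 higher, median -0.14, adjusted p = 0.0346, and adjusted p = 0.1 with an estimated correlation), with CHLH at -1.76 and CAB2R at -1.26, and this call ended with array weights (adjusted p = 0.0748). The DNA replication and aquaporin calls also ended among the brighter genes (adjusted p = 0.592 and 0.0991).

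In BRG-20, small heat shock protein genes, HSFA2A and CLPB1 were among the largest rises. Phytoalexin enzymes were lower, with the lowest median of the 6 genotypes. Glutathione S-transferase, ABC transporter, jasmonate, cytokinin and nitrogen genes were higher with the preset correlation only. For these 5 lists the adjusted p-values with an estimated correlation were 0.0708, 0.291, 0.172, 0.11 and 0.0708. Of the probesets, 5029 were higher and 5564 lower, 10593 in all (18.5%), and 1703 changed at least 2-fold. Quantile normalization of all arrays gave 17023. Of 8143 called genes, 679 rose and 417 fell at least 2-fold, and the groups did not overlap in 45.4% of genes, where chance gives 10%.

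The named genes that rose most in BRG-20 were HSP18.1 (5.82, standard error 0.138, adjusted p = 1.61e-21), HSP17.4 (5.75), HSP18.6 (5.40), HSFA2A (4.79), CLPB1 (3.95), GSTZ5 (3.81), HSP21.9 (3.62), HSP17.7 (3.57), OPR6 (3.00) and HSP16.9B (3.00). The largest falls of such genes were those of PBZ1 (-3.31), LTP2-B (-3.13), DXPS (-3.10), CPS2 (-2.70), CYP99A2 (-2.64), ICL (-2.52), the vacuolar iron transporter gene VIT1.2 (-2.47), CYP71Z7 (-2.47), the cystatin gene OC-X (-2.45) and KSL7 (-2.39).

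In BRG-20, 15 lists were called, 13 higher and 2 lower, and 2 of them, the small heat shock proteins and the phytoalexin enzymes, also with an estimated correlation. Of list members, 607 were called over all genes and 619 adjusted over the list alone. The small heat shock proteins were higher (15 of 19 genes higher and 2 lower, median 1.43, adjusted p = 7.49e-09, and adjusted p = 0.0043 with an estimated correlation). The heat shock factors were higher (11 of 20 genes higher and 3 lower, median 0.60, adjusted p = 0.000246, and adjusted p = 0.11 with an estimated correlation), with HSFA3 at 2.05. The large chaperones were higher (13 of 30 genes higher and 4 lower, median 0.11, adjusted p = 0.0235, and adjusted p = 0.325 with an estimated correlation). The diterpenoid phytoalexin enzymes were lower (12 of 16 genes lower, 0 higher, median -1.53, adjusted p = 4.51e-08, and adjusted p = 0.000178 with an estimated correlation). So were the cytochrome P450s (15 of 29 genes lower and 5 higher, median -0.30, adjusted p = 0.036, and adjusted p = 0.108 with an estimated correlation). The fall of the phytoalexin list differed from the response of BRG-12, BRG-15, CN1646-5 and CN1646-2 but not from that of NAYANMONI. The P450 call ended without arsenate replicate 2 (adjusted p = 0.0554). Among the brighter genes the calls of heat shock factors (adjusted p = 0.224), large chaperones (adjusted p = 0.374) and P450s (adjusted p = 0.337) ended. Under quantile normalization those of the large chaperones and the P450s did (adjusted p = 0.0562 for each). Glutathione S-transferases were higher (5 of 6 genes higher, 0 lower, median 1.30, adjusted p = 8.84e-05, and adjusted p = 0.0708 with an estimated correlation), with GST1 at 2.56. ABC transporters were higher (8 of 13 genes higher, 0 lower, median 0.45, adjusted p = 0.00625, and adjusted p = 0.291 with an estimated correlation), with mdr17 at 2.28.

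Hormone and nutrient lists were higher in BRG-20 as well. Cytokinin genes were higher (13 of 31 genes higher and 2 lower, median 0.23, adjusted p = 0.00156, and adjusted p = 0.11 with an estimated correlation), with LOG at 1.18 and RR4 at 1.16. Jasmonate genes were higher (18 of 37 genes higher and 5 lower, median 0.22, adjusted p = 0.00625, and adjusted p = 0.172 with an estimated correlation), with OPR1 at 2.39. Protein phosphatases 2C were higher (26 of 55 genes higher and 10 lower, median 0.15, adjusted p = 0.0141, and adjusted p = 0.308 with an estimated correlation), with PP2C30 at 2.30. Nitrogen genes were higher (8 of 21 genes higher, 0 lower, median 0.34, adjusted p = 0.0141, and adjusted p = 0.0708 with an estimated correlation), with the glutamine synthetase gene GLN1-2 at 1.92 and NIA1 at 1.82. Sugar genes were higher (21 of 47 genes higher and 6 lower, median 0.10, adjusted p = 0.036, and adjusted p = 0.268 with an estimated correlation), although SWEET14 (-2.02) fell where SWEET1B (2.07) rose. Of the cell wall lists, the cellulose synthase family was higher (15 of 29 genes higher and 5 lower, median 0.31, adjusted p = 0.0235, and adjusted p = 0.208 with an estimated correlation), with CSLF6 at 1.85 and CESA6 at 1.64. The lignin enzymes were higher (11 of 29 genes higher and 5 lower, median 0.09, adjusted p = 0.0235, and adjusted p = 0.0708 with an estimated correlation), with LAC10 at 2.09. The ribosomal proteins were higher (9 of 23 genes higher, 0 lower, median 0.11, adjusted p = 0.0235, and adjusted p = 0.308 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.117). The calls of sugar genes (adjusted p = 0.14), cellulose synthases (adjusted p = 0.224), lignin enzymes (adjusted p = 0.145) and ribosomal proteins (adjusted p = 0.0899) ended among the brighter genes. The 18S ribosomal RNA control probeset was 4.14 higher with arsenate in BRG-20, from a control mean of 3.02 (SD 2.16, n = 3) to 7.16 (SD 1.33, n = 3).

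CN1646-5 and CN1646-2 are breeding lines to which the labels give the same parents, Pusa Basmati 1 and IR 64. In CN1646-5, expansin, aquaporin, iron homeostasis and photosynthesis genes were lower. Abscisic acid and desiccation genes and small heat shock protein genes were higher, and DNA replication and fermentation genes lower, with the preset correlation only. For these 4 lists the adjusted p-values with an estimated correlation were 0.0585, 0.17, 0.311 and 0.159. Of the probesets, 6400 were higher and 5898 lower, 12298 in all (21.5%), and 1756 changed at least 2-fold. Of 8369 called genes, 364 rose and 700 fell at least 2-fold, and the groups did not overlap in 55.3% of genes, where chance gives 10%.

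Named genes with the largest rises in CN1646-5 were HSFA2A (3.43), HSP18.1 (2.83), RAB21 (2.78), LEA19 (2.69), HSP26.2 (2.61), RAB16B (2.45), HSP17.4 (2.44), ICL (2.18), CLPB-M (2.17) and TPP3 (2.11). The largest falls of such genes were those of NSHB2 (-4.73, standard error 0.084, adjusted p = 7.12e-24), the expansin genes EXPA3 (-3.50), EXPB2 (-3.46) and EXPB7 (-2.87), NIA1 (-2.89), CAB2R (-2.77), TBL6 (-2.64), the potassium channel gene AKT1 (-2.47) and GER1 (-2.47). HSFA2C fell by 3.04 on 1 probeset and was called higher on its other probeset (1.96).

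In CN1646-5, 16 lists were called, 3 higher and 13 lower, and 7 of them also with an estimated correlation. Of list members, 621 were called over all genes and 628 adjusted over the list alone. The expansins were lower (17 of 30 genes lower and 1 higher, median -0.52, adjusted p = 2.29e-07, and adjusted p = 0.00014 with an estimated correlation), with EXPA8 at -2.33. The aquaporins were lower (15 of 25 genes lower and 1 higher, median -0.28, adjusted p = 0.000164, and adjusted p = 0.0015 with an estimated correlation), with Lsi6 at -2.22 and TIP2-1 at -2.04. Iron homeostasis genes were lower (11 of 29 genes lower and 2 higher, median -0.26, adjusted p = 0.00229, and adjusted p = 0.00761 with an estimated correlation), with NAS1 at -2.13, NAAT1 at -1.82 and VIT1.2 at -1.82. Lignin enzymes were lower (14 of 29 genes lower and 4 higher, median -0.18, adjusted p = 0.00783, and adjusted p = 0.0212 with an estimated correlation), with 4CL1 at -1.73 and CAD6 at -1.72. Nitrogen genes were lower (9 of 21 genes lower and 2 higher, median -0.21, adjusted p = 0.0115, and adjusted p = 0.049 with an estimated correlation), GLN1-2 with -1.61, although GLN1-3 rose by 1.65. The phytoalexin enzymes were lower (11 of 16 genes lower and 2 higher, median -0.37, adjusted p = 0.0115, and adjusted p = 0.0321 with an estimated correlation). The photosynthesis genes were lower (14 of 19 genes lower, 0 higher, median -0.77, adjusted p = 1.29e-07, and adjusted p = 0.000245 with an estimated correlation), with GOS5 at -1.61 and PETE at -1.47.

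The remaining calls in CN1646-5 were made with the preset correlation only. DNA replication and cell cycle genes were lower (36 of 81 genes lower and 9 higher, median -0.25, adjusted p = 0.00229, and adjusted p = 0.311 with an estimated correlation), with CYCB1-1 at -1.33. Hypoxia genes were lower (7 of 13 genes lower and 2 higher, median -0.44, adjusted p = 0.0116, and adjusted p = 0.159 with an estimated correlation). Germin-like proteins were lower (7 of 9 genes lower, 0 higher, median -0.83, adjusted p = 0.000259, and adjusted p = 0.0557 with an estimated correlation). The cellulose synthase family was lower (11 of 29 genes lower and 3 higher, median -0.25, adjusted p = 0.0116, and adjusted p = 0.156 with an estimated correlation). Metallothioneins were lower (4 of 7 genes lower, 0 higher, median -0.31, adjusted p = 0.0174, and adjusted p = 0.172 with an estimated correlation), with MT2B at -2.26. The cytochrome P450s were lower (16 of 29 genes lower and 5 higher, median -0.32, adjusted p = 0.0272, and adjusted p = 0.0585 with an estimated correlation), a call that ended without arsenate replicate 3 (adjusted p = 0.0539). Abscisic acid and desiccation genes were higher (15 of 27 genes higher and 5 lower, median 0.28, adjusted p = 0.00229, and adjusted p = 0.0585 with an estimated correlation). So were the clock genes (5 of 7 genes higher and 1 lower, median 0.59, adjusted p = 0.0174, and adjusted p = 0.22 with an estimated correlation), with PRR95 at 1.24. The small heat shock proteins were higher (11 of 19 genes higher and 3 lower, median 0.52, adjusted p = 0.0123, and adjusted p = 0.17 with an estimated correlation), a call that ended under quantile normalization of all arrays (adjusted p = 0.0599), as did that of the metallothioneins (adjusted p = 0.0572). Among the brighter genes the calls of DNA replication (adjusted p = 0.462), cellulose synthases (adjusted p = 0.227), metallothioneins (adjusted p = 0.0504), P450s (adjusted p = 0.0611), abscisic acid genes (adjusted p = 0.0602) and small heat shock proteins (adjusted p = 0.185) ended. That of the clock genes ended with the probesets of each gene averaged (adjusted p = 0.112). The 3' minus 5' difference of GAPDH rose by 1.33 with arsenate in this line, while that of actin rose by only 0.213 (control SD 0.638, n = 3).

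NAYANMONI, which the labels call an aus rice, was set apart by its labelled response. An exchange of its control and arsenate labels was not excluded, and every rise below would then be a fall and every fall a rise. The iron transporter gene IRT2, the silicon transporter genes Lsi1, Lsi2 and Lsi6 and the fermentation genes PDC1 and PDC2 rose in it, while the iron homeostasis list was not called (adjusted p = 0.528). Jasmonate, NAC factor, pathogenesis related, phytoalexin, expansin and photosynthesis genes were lower. The heat shock genes HSP18.1 and HSFA2A were not called on their chosen probesets, though HSFA2A was called lower with its probesets averaged (-0.33, adjusted p = 0.0181). Of 197 genes called alike in the other 5 genotypes, 85 (43.1%) moved the same way in NAYANMONI. Of the probesets, 5673 were higher and 4574 lower, 10247 in all (17.9%), and 2007 changed at least 2-fold. Of 7504 called genes, 494 rose and 751 fell at least 2-fold, and the groups did not overlap in 74.9% of genes, where chance gives 33.3%.

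The largest rises of named genes in NAYANMONI were those of the iron transporter gene IRT2 (3.66, standard error 0.157, adjusted p = 2e-15), PDC1 (3.28), CPDK2 (3.03), NSHB2 (2.80), Nramp1 (2.27), MYBAS1 (2.08), Lsi1 (2.03), Lsi6 (2.02), PDC2 (1.89) and Lsi2 (1.88). The largest falls of such genes were those of TBT2 (-3.54), CPS2 (-3.15), MT2B (-2.62), CYP76M5 (-2.27), the ABC transporter gene ABCG36 (-2.24), CFBP1 (-2.18), PBZ1 (-2.15), a cyclin gene, LOC4342121 (-2.07), EXPB3 (-1.95) and LFNR1 (-1.92).

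In NAYANMONI, 12 lists were called, 1 higher and 11 lower, and 6 of them also with an estimated correlation. Of list members, 557 were called over all genes and 572 adjusted over the list alone. Jasmonate genes were lower (24 of 37 genes lower and 2 higher, median -0.52, adjusted p = 1.2e-07, and adjusted p = 0.00657 with an estimated correlation), with JAZ8 at -1.79, LOX1.1 at -1.58 and JAZ11 at -1.13. NAC factors were lower (7 of 8 genes lower, 0 higher, median -0.61, adjusted p = 7.66e-05, and adjusted p = 0.00452 with an estimated correlation), with NAC4 at -1.58 and NAC5 at -1.39. Pathogenesis related proteins were lower (12 of 20 genes lower and 1 higher, median -0.52, adjusted p = 0.000291, and adjusted p = 0.00667 with an estimated correlation), with Cht10 at -1.44. The phytoalexin enzymes were lower (11 of 16 genes lower and 1 higher, median -0.70, adjusted p = 4.03e-05, and adjusted p = 0.00205 with an estimated correlation), a call that ended among the brighter genes alone (adjusted p = 0.143). Expansins were lower (16 of 30 genes lower and 2 higher, median -0.37, adjusted p = 0.00104, and adjusted p = 0.00492 with an estimated correlation). The photosynthesis genes were lower (13 of 19 genes lower and 1 higher, median -0.91, adjusted p = 2.64e-07, and adjusted p = 0.000812 with an estimated correlation).

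Calls in NAYANMONI made with the preset correlation only were the following. Hypoxia and fermentation genes were higher (6 of 13 genes higher and 1 lower, median 0.34, adjusted p = 0.00213, and adjusted p = 0.0935 with an estimated correlation), with Adh2 at 1.59. DNA replication and cell cycle genes were lower (40 of 81 genes lower and 6 higher, median -0.35, adjusted p = 7.69e-07, and adjusted p = 0.0942 with an estimated correlation), with PCNA at -0.99. Ribosomal proteins were lower (10 of 23 genes lower, 0 higher, median -0.24, adjusted p = 0.000346, and adjusted p = 0.103 with an estimated correlation), with CL18 at -1.45. Abscisic acid and desiccation genes were lower (12 of 27 genes lower and 2 higher, median -0.19, adjusted p = 0.00923, and adjusted p = 0.108 with an estimated correlation), in the opposite direction to both CN1646 lines, with PP2C30 at -1.84. Cytochrome P450s were lower (12 of 29 genes lower and 6 higher, median -0.13, adjusted p = 0.0248, and adjusted p = 0.0541 with an estimated correlation). Aquaporins were lower (8 of 25 genes lower and 3 higher, median -0.14, adjusted p = 0.0376, and adjusted p = 0.0554 with an estimated correlation), a call that ended without control replicate 2 (adjusted p = 0.0752) and under quantile normalization (adjusted p = 0.0755). The glutathione S-transferases had 5 of 6 genes called higher with a median of 0.32, but the list was not called (adjusted p = 0.134).

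In CN1646-2, ribosomal proteins were higher and so, unlike the other genotypes with a call, were phytoalexin enzymes, and the nicotianamine synthase genes NAS1 and NAS2 rose. Small heat shock protein, DNA replication and proteasome genes were higher and fermentation genes and WRKY factors lower with the preset correlation only. For these 5 lists the adjusted p-values with an estimated correlation were 0.123, 0.203, 0.209, 0.203 and 0.209. Of the probesets, 7439 were higher and 6676 lower, 14115 in all (24.7%), and 3205 changed at least 2-fold. The balance turned to 6310 higher and 7472 lower after a shift to a common median, and to 7554 and 7684 under quantile normalization. Of 9585 called genes, 1360 rose and 780 fell at least 2-fold, and the groups did not overlap in 59.2% of genes, where chance gives 10%.

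In CN1646-2, the named genes that rose most were HSP18.1 (6.32, standard error 0.138, adjusted p = 1.48e-22), HSFA2A (6.30), HSP17.4 (5.95), the nicotianamine synthase genes NAS1 (5.92) and NAS2 (5.09), RAB21 (5.00), CLPB1 (4.97), HSP18.6 (4.58), HSP16.0 (4.34) and CLPB-M (4.33). The largest falls of such genes were those of the peroxidase gene LOC4344277 (-6.18), NSHB2 (-4.16), CPDK2 (-4.10), PDC1 (-3.48), TPP7 (-3.15), the ethylene receptor gene ETR2 (-2.84), VIT1.2 (-2.82), ARGOS (-2.79), WRKY76 (-2.78) and PDC2 (-2.77).

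In CN1646-2, 9 lists were called, 7 higher and 2 lower, and 2 of them, the ribosomal proteins and the phytoalexin enzymes, also with an estimated correlation. Of list members, 731 were called over all genes and 746 adjusted over the list alone. The ribosomal proteins were higher (22 of 23 genes higher, 0 lower, median 1.02, adjusted p = 1.98e-10, and adjusted p = 0.0118 with an estimated correlation), with RPS26 at 1.53 and RPL7A-2 at 1.47. The diterpenoid phytoalexin enzymes were higher (11 of 16 genes higher, 0 lower, median 1.06, adjusted p = 6.92e-05, and adjusted p = 0.00466 with an estimated correlation), with CPS2 at 2.92, KSL7 at 2.43, CYP99A2 at 2.42 and CYP71Z7 at 2.39. Genes of DNA replication and cell cycle were higher (48 of 81 genes higher and 6 lower, median 0.43, adjusted p = 1.7e-05, and adjusted p = 0.203 with an estimated correlation), with PCNA at 2.16, CYCB1-1 at 2.15 and MCM2 at 2.05. So were proteasome genes (16 of 24 genes higher, 0 lower, median 0.39, adjusted p = 0.00445, and adjusted p = 0.209 with an estimated correlation), with Ub-CEP52-2 at 1.51.

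The small heat shock proteins were higher in CN1646-2 (10 of 19 genes higher and 2 lower, median 0.43, adjusted p = 0.000482, and adjusted p = 0.123 with an estimated correlation), with a mean of 1.78. The heat shock factors were higher (13 of 20 genes higher and 4 lower, median 0.49, adjusted p = 0.0203, and adjusted p = 0.324 with an estimated correlation). Abscisic acid and desiccation genes were higher (16 of 27 genes higher and 6 lower, median 0.36, adjusted p = 0.0103, and adjusted p = 0.203 with an estimated correlation), with PP2C30 at 3.46 and RAB16B at 3.30. Hypoxia genes were lower (7 of 13 genes lower and 2 higher, median -0.83, adjusted p = 0.00525, and adjusted p = 0.203 with an estimated correlation), although their list member AOX1a rose by 2.99. So were the WRKY factors (6 of 6 genes lower, 0 higher, median -0.62, adjusted p = 0.00907, and adjusted p = 0.209 with an estimated correlation). Among the brighter genes the calls of DNA replication (adjusted p = 0.0735), heat shock factors (adjusted p = 0.495), abscisic acid genes (adjusted p = 0.129), hypoxia genes (adjusted p = 0.0708) and WRKY factors (adjusted p = 0.0735) ended. The hybridization control probesets bioB and cre were lower in the arsenate arrays of this line, by -0.807 and -0.641, and the 3' probeset of a fungal elongation factor fell by 2.411.

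Whether the response differed between genotypes was tested directly. Sizes of change were compared on the deposited scales, which differ between most genotypes. By the labels, the widest range of log2 change belonged to LOC4343847, a gene known here only by its locus number, and among genes with a name to PDC1, NAS1 and a peroxidase gene, LOC4344277. The upper end of the LOC4343847 and LOC4344277 ranges lies in NAYANMONI, so their size rests on its labels, as does the place of LOC4344277, while those of PDC1 and NAS1 end in other genotypes. Many genes rose in some genotypes and fell in others. The response differed for 21354 probesets (37.3%) and for 13562 genes (75.7%). Over the 15 pairs of genotypes, 146581 probeset differences were called in sum. By the labels, NAYANMONI and CN1646-2 were furthest apart, with 14518 probesets and a Pearson r of -0.414 across genes, which are not independent replicates. Of their genes, 3956 were called in opposite directions, where independent lists would share 2000. Every value of a pair with NAYANMONI rests on the labels of its 4 arrays, and an exchange of its control and arsenate labels, which would turn the sign of r, was not excluded. BRG-20 and CN1646-2 were most alike in r (0.49), with 2143 genes higher in both, where independent lists would share 1030, and 2234 lower in both, where they would share 1140. The BRG-20 group includes the arsenate array whose description gives the parents of the CN1646 lines, and r without it was not computed. BRG-12 and BRG-15 had the fewest differences (5027 probesets), both with few arrays. CN1646-5 and CN1646-2, with the same labelled parents, differed at 12306 probesets and had an r of 0.289.

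**Figure D3:**
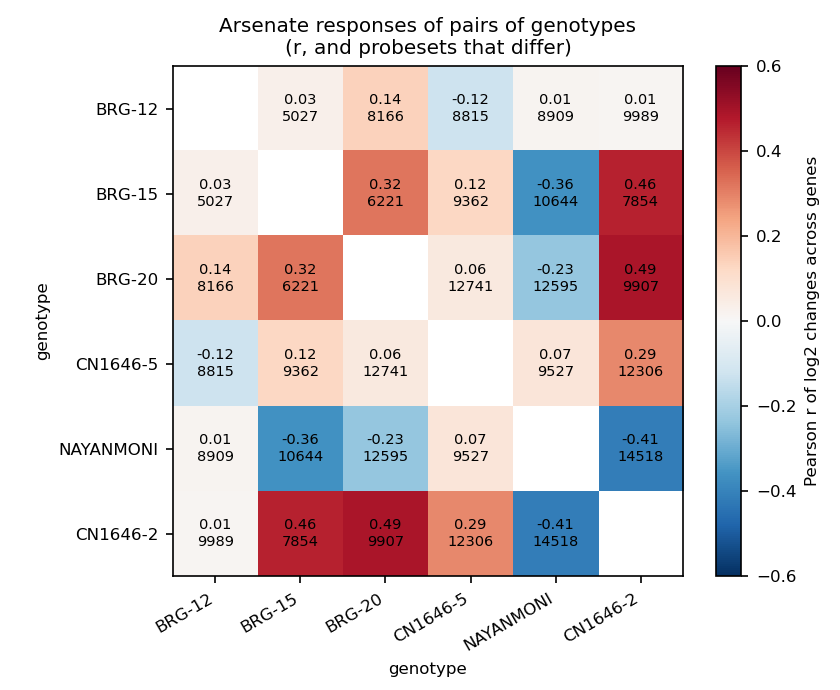
Each square gives the Pearson r, across 17905 genes, of the log2 changes of a pair of genotypes, with the number of probesets whose change differed at an adjusted p under 0.05. The r is -0.414 for NAYANMONI and CN1646-2 and 0.49 for BRG-20 and CN1646-2.

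PDC1 had the widest range among named genes, rising by 3.43 in BRG-12, 3.28 in NAYANMONI and 2.12 in BRG-20, with -5.66 in BRG-15, -3.48 in CN1646-2 and -1.86 in CN1646-5 (adjusted p = 6.44e-21 for the difference). NSHB2 had the same signs in each genotype, from -4.73 in CN1646-5 to 2.80 in NAYANMONI, and CPDK2 ran from -4.10 in CN1646-2 to 3.03 in NAYANMONI, so both ranges rest on the NAYANMONI labels. The 5 hypoxia genes Adh2, PDC1, PDC2, NSHB1 and NSHB2 all moved the same way within 5 of the 6 genotypes. NAS1 rose by 5.92 in CN1646-2, 2.91 in BRG-20 and 1.74 in BRG-15, and was at -2.13 in CN1646-5. HSFA2A ran from -1.42 in BRG-12 to 6.30 in CN1646-2. Of 675 combinations of a list with a pair of genotypes, 195 differed, and 66 of them also with an estimated correlation. The phytoalexin enzymes differed in 11 of 15 pairs under both tests.

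**Figure D4:**
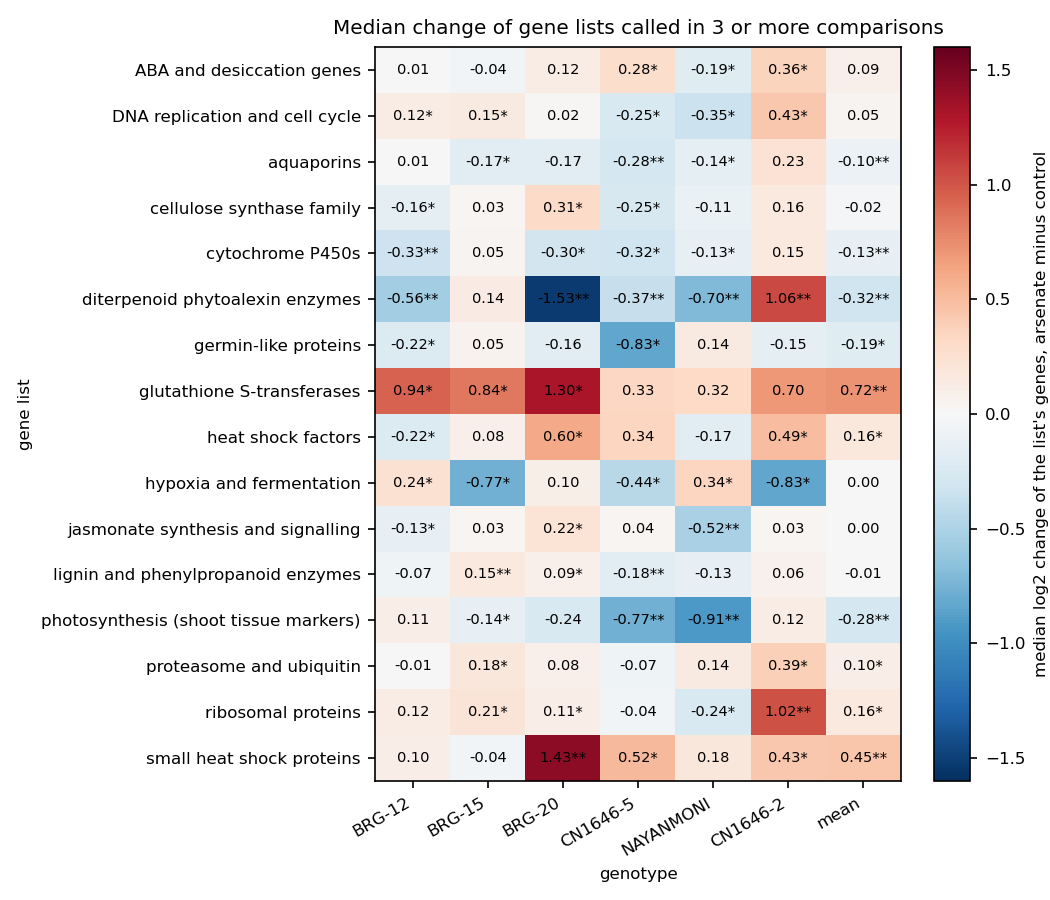
Each cell gives the median log2 change of a list's genes, arsenate minus control, for the lists called in 3 or more of the 7 comparisons. One asterisk marks an adjusted p under 0.05 with the preset correlation and a pair of asterisks the same also with an estimated correlation, and the phytoalexin row runs from -1.53 in BRG-20 to 1.06 in CN1646-2.

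Levels in the control roots were compared between genotypes only as counts, because the deposited values of most genotypes lie on different scales. All 57258 probesets differed between the 6 control groups on the deposited scales, and 42592 did after quantile normalization of all arrays. Between the control roots of CN1646-2 and CN1646-5, 57219 probesets differed, 37 higher and 57182 lower, with a median difference of -3.81 that is a property of the scale. After quantile normalization of all arrays the count was 21889, with 10814 higher and 11075 lower, and after a shift to a common median it was 31634 higher and 13931 lower. No genes are named from these comparisons.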

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

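The tests of exchanged labels, of RNA integrity, of oxygen supply and of single arrays were chosen only after the result was seen, and the rank test, the matched lists and the splits were not. The response differed between genotypes for 13562 genes, and 195 combinations of a list and a pair of genotypes differed by camera. The phytoalexin, DNA replication, photosynthesis, ribosomal protein and small heat shock protein lists differed in 11 of 15 pairs each, the abscisic acid, expansin and heat shock factor lists in 10, the hypoxia list in 9, and the cellulose synthase and P450 lists in 8. With an estimated correlation 66 of the 195 differences were called. The phytoalexin list kept all 11 of its pairs, photosynthesis 8, expansins 7, ribosomal proteins 5, small heat shock proteins and P450s 4 each, hypoxia 3, abscisic acid 2, the cellulose synthases 1, and DNA replication and heat shock factors 0. By the labels, the widest ranges of log2 change over the genotypes were those of LOC4343847 (12.13), LOC4348268 (9.51), PDC1 (9.09), LOC4351721 (8.90), LOC4343616 (8.57), LOC4344575 (8.52), LOC4333962 (8.24), NAS1 (8.05), LOC4338958 (8.03) and the peroxidase gene LOC4344277 (7.80). Among genes with a name, HSFA2A (7.72), NSHB2 (7.53), CPDK2 (7.12), LTP2-B (6.55), HSP18.1 (6.20), a further peroxidase gene, LOC4339222 (6.17), and HSP18.6 (6.09) came next. LOC4343847 ran from -6.79 in CN1646-2 and -6.52 in CN1646-5 to 5.34 in NAYANMONI, the same signs as the hypoxia genes in these genotypes. The ranges of LOC4343847, LOC4348268, LOC4343616, LOC4344277, NSHB2 and CPDK2 have an end in NAYANMONI, so their size, and the order of most of them, rest on its labels, for which an exchange was not excluded.

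Control probesets outside the comparisons moved with arsenate in some genotypes. The 18S ribosomal RNA probeset was 4.14 higher in BRG-20, the 5.8S probeset 1.66 higher in CN1646-5 and a cyclophilin 3' probeset 2.04 higher in CN1646-2, where a fungal elongation factor 3' probeset fell by 2.411. The 3' minus 5' difference of GAPDH was 2.15 higher with arsenate in BRG-12 and 1.33 higher in CN1646-5. That of actin was 0.893 higher in BRG-12 but only 0.213 higher in CN1646-5 (control SD 0.638), so less intact arsenate RNA is shown by both measures in BRG-12 and by GAPDH alone in CN1646-5. Genes called in BRG-12 and CN1646-5 alone may therefore partly reflect RNA integrity, and without both genotypes the mean calls of the P450s (adjusted p = 0.464), the aquaporins (adjusted p = 0.545) and the germin-like proteins (adjusted p = 0.33) ended.

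By the labels, NAYANMONI and CN1646-2 responded in opposite directions, with 3956 genes called opposite ways. The intervals below count genes as independent, which genes measured on the same arrays are not, so they understate the uncertainty. An exchange of the control and arsenate labels in CN1646-2 is argued against, since of 56 genes called alike in the other 5 genotypes 50 moved the same way there (89.3%, 95% Clopper-Pearson interval 78.1 to 96), with a median signed change of 1.051, and a loss of RNA integrity is argued against by a largest GAPDH shift of 0.206 in these genotypes. An exchange in NAYANMONI stays open, because of 197 genes called alike in the other 5 genotypes only 85 moved the same way there (43.1%, interval 36.1 to 50.4), with a median signed change of -0.209, and although 36 genes higher and 54 genes lower in the others were called the other way, 31 and 18 were called the same way, LAC3, LOC4334183 and LOC4347027 among them. Oxygen supply that differed between culture vessels also stays open, because 5 hypoxia genes (Adh2, PDC1, PDC2, NSHB1 and NSHB2) moved together in 5 of the 6 genotypes, with medians of 1.43 in BRG-12, -1.37 in BRG-15, -2.22 in CN1646-5, 1.89 in NAYANMONI and -2.77 in CN1646-2, and the vessels cannot be told apart from the groups. A difference between the genotypes in their arsenate response remains an open and untested explanation.

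The small heat shock protein list was called higher in BRG-20, CN1646-5 and CN1646-2, but with an estimated correlation only in BRG-20 (adjusted p = 0.17 in CN1646-5 and 0.123 in CN1646-2), and in CN1646-5 the call also ended under quantile normalization (adjusted p = 0.0599) and among the brighter genes (adjusted p = 0.185). The value scale of the genotypes is argued against for BRG-20 and CN1646-2, since the list's median percentile rank within the array rose by 13.65 and 7.52 points there, against 0.94 in BRG-12, -0.32 in BRG-15 and 1.59 in NAYANMONI. For CN1646-5, with 3.48 points, the scale was not excluded. A single array is argued against for BRG-20 and CN1646-2, where the lowest median with 1 array left out was 0.363 and the list stayed called. A genotype difference in the heat shock response to arsenate is a candidate explanation, but a difference in temperature or handling between vessels was not tested and stays open.

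Ribosomal protein genes rose in CN1646-2, with a median of 1.02 over 23 genes. A shift of all bright genes is argued against, since the highest median of 10000 lists of other genes matched on level was 0.746, and 95% of them lay between -0.265 and 0.249. A single array is argued against, since the lowest median with 1 array left out was 0.997. A change in growth was not tested and stays open, since the rises of DNA replication and proteasome genes in the same line were not called with an estimated correlation (adjusted p = 0.203 and 0.209). Batch or vessel effects that follow the treatment could not be separated from it.

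In the mean response, 1 of 100 splits of the arrays within genotypes, the real one, called as many probesets (10802, highest other 6989). For lists, 3 of 100 splits, the real one included, called as many (13, highest other 15). Both shares are under 0.05, which argues against chance labels in all genotypes at once, if the arrays are independent. It does not show a response shared by the genotypes. For single genotypes the 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real values and the highest of the other splits were 10593 and 25 probesets in BRG-20, 12298 and 30 in CN1646-5, 14115 and 2 in CN1646-2, and 57219 and 0 between the controls of CN1646-2 and CN1646-5. For lists they were 15 and 8 in BRG-20, 16 and 10 in CN1646-5, and 9 and 6 in CN1646-2.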

How the results depend on the processing

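Leaving out NAYANMONI, or BRG-12 with CN1646-5, and averaging the probesets of named genes were chosen only after the result was seen. Most results kept their direction and their side of the threshold. Of 980 gene values, 964 did so with the replicate block, 947 under quantile normalization, 958 after a shift to a common median and 944 with array weights. Of 85 list calls, 83 did so with the block, 79 under quantile normalization, 85 with an intensity trend and 57 among the brighter probesets, where fewer genes were tested. With an estimated correlation 27 did so, and the lists called fell from 13 to 7 in the mean response and from 72 to 20 over the genotypes. The cause of the following moves was not tested unless named. Quantile normalization of all arrays gave 17023 probesets in BRG-20 and 21889 between the CN1646-2 and CN1646-5 controls. Array weights gave 13944 in BRG-12 and 10057 in BRG-15. A fit of BRG-12 alone gave 1056, and the additive model gave 4756 in the mean response. In the additive model, unlike the main fit, differences between the genotypes' responses enter the residual spread. The brighter probesets, with fewer tested, gave 28629 among controls and 28591 between the 2 lines. With fewer pairs of genotypes, the pairwise differences summed to 86155 without NAYANMONI and 63821 without BRG-12 and CN1646-5. Averaging all probesets reversed HSFA2C in BRG-12 (-0.35), in CN1646-2 (0.52) and in the mean (0.08). It also reversed HSFA2A in NAYANMONI, which was not called on its 1 chosen probeset but was called lower when averaged (-0.33, adjusted p = 0.0181 from limma). Without BRG-12 and CN1646-5 the mean reversed for Lsi6 (0.026) and TIP2-1 (0.26), since the largest falls of both were in those genotypes.

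With each array left out in turn, the counts ran from 3265 to 5174 in BRG-12, 3621 to 6240 in BRG-15, 9221 to 11102 in BRG-20, 10741 to 12947 in CN1646-5, 6896 to 10782 in NAYANMONI, 12730 to 14661 in CN1646-2 and 9814 to 11054 in the mean. They ran from 20035 to 21772 for the difference between genotypes, 133510 to 151150 for the pairs, 57258 to 57258 among controls, 57206 to 57222 between the 2 lines' controls, 13 to 14 for lists in the mean and 69 to 74 for lists per genotype. The count of BRG-12 moved by over 1.5 times without control replicate 2 (3265), and that of BRG-15 without control replicate 1 (3621), control replicate 2 (3811), arsenate replicate 1 (3708) or arsenate replicate 2 (3710). A lone array left in a group was assumed to vary like the other groups. Of 15 pairs of arrays with the same number, 1 correlated above 0.1, so the replicate block is given only as an alternative. The block ended the list calls of photosynthesis in BRG-15 (adjusted p = 0.0711) and large chaperones in the mean (adjusted p = 0.0562). Without detection calls, signal over background could not be given.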

Other observations

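No test in this part was chosen after the result was seen. Several lists on the handling of arsenic and oxidative stress were not called in the mean response or in any single genotype. In the mean response, sulfur assimilation and thiol synthesis had 3 of 10 genes higher and 1 lower, antioxidant enzymes 7 of 21 higher and 7 lower, and glutaredoxins and thioredoxins 10 of 39 higher and 7 lower. Phosphate uptake and signalling had 4 of 22 genes higher and 6 lower, metal transporters 7 of 27 higher and 9 lower, and potassium and sodium transporters 6 of 26 higher and 7 lower. Between genotypes the response of the antioxidant enzymes differed in 4 of the 15 pairs and that of the metal transporters in 1, none of them with an estimated correlation.

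Regulatory lists without a call in the mean response or in a single genotype also held members that rose and members that fell. In the mean response, MYB factors had 2 of 11 genes higher and 5 lower, ERF and DREB factors 2 of 10 higher and 4 lower, and bHLH factors 1 of 10 higher and 1 lower. Auxin signalling had 14 of 59 higher and 8 lower, ethylene genes 3 of 11 higher and 4 lower, and MAP kinases 6 of 15 higher and 2 lower. The root tip and endodermis markers (5 of 25 higher, 6 lower) and the seed storage proteins and amylases (3 of 16 higher, 4 lower), which mark particular tissues, were not called there either. Between genotypes the bHLH factors differed in 3 pairs, the ERF and DREB factors in 2, and the MYB factors and the root tip and endodermis markers in 1 each, none of them with an estimated correlation.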
